A study of Danio rerio with 20 samples.

How the data were processed

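Muscle of male zebrafish of the strain given as AB JxTu was measured in 20 libraries by sequencing of total RNA prepared with the TruSeq RNA Library Prep Kit v2. The 4 groups of 5 libraries follow the labels of age (1 year or 3 years) and perturbation (none or swim-tunnel). The labels give no replicate number, date, time of day, batch or pairing, so libraries are numbered within each group in the order of their sample records. The processing notes name bcl2fastq 1.8.4, STAR 2.4.1d, featureCounts 1.4.6-p4 and the genome build GRCz10, without the annotation release, the strand setting or the treatment of reads that fit several genes. Paralogues such as fast myosin or trypsin genes can therefore share reads.

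The deposited main table holds raw counts per Ensembl gene, in whole numbers. A further deposited table, named as RPKM, was read as a score: tested on the 406 genes with counts and values of at least 50 in every library, the lengths implied by each library's own total varied with a median coefficient of variation of 0.133, and those implied by library totals taken in turn down the table with 1.17e-06. With totals taken in turn, 99.5% of implied lengths lay within 0.02 bases of a whole number, against 8.36% with own totals. Its columns sum to 517053 to 789719 and follow the count totals (Pearson r = 0.940 over the 20 libraries). The main results rest on the counts, and the deposited scaled values serve as alternatives, as does RPKM recomputed with each library's own total.

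Genes were kept by filterByExpr of edgeR 4.0.16 on the 4 groups (17025 of 32105 genes), library sizes were scaled by TMM, and 1 model of the 4 group means was fitted with robust dispersions and tested with the quasi-likelihood F-test in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes under 0.05 are called. The common dispersion was 0.163, a biological coefficient of variation of 0.404. For 40 pairs of replicates the chi-square of the counts per degree of freedom was 42.7 to 244, so replicates differ far beyond counting error. Depth was 3.16e+07 to 4.89e+07 counts per library, and the standard errors given with each change carry the precision that depth and replicates allow. The comparisons are the swim effect at each age, the age effect with and without exercise, their interaction, and as secondary results both averaged effects. Standard deviations are over the 5 libraries of a group, CPM are edgeR values on TMM-scaled library sizes, and log2 changes carry standard errors from the fit. No batch is given in the labels, so none was fitted.

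Gene lists, comparisons, the naming rule and most alternatives were fixed before the data were examined. The rule names, per comparison, called genes with a mean log2 CPM of at least 2, a proper symbol read without regard to case, and all 5 libraries of one group on the same side of the other group's median: the 8 with the highest and the 8 with the lowest log2 change, then up to 2 called members of each list with the smallest adjusted p, at most 30 genes, or 10 for the averaged effects. 1 gene this rule gives is not reported here; counts of called genes and list members include it. A panel of 17 genes with any result could be named too (20 identifiers, since some symbols fit more than 1), of which 1, 0, 2, 5 and 1 were called in the 5 comparisons. Of 1723 list names 1642 were matched, 1244 by symbol, 191 by another name and 207 without the paralogue letter. 36 lists with at least 5 tested genes were tested with camera of limma 3.58.1 on voom values at a preset correlation of 0.01, beside camera with an estimated correlation and fry, which asks whether a list's genes move one way and does not compare them with other genes. An exact permutation test of list scores (252 orderings of 5 against 5, smallest p 0.00794; for the interaction, swim labels permuted within each age) was chosen after seeing the data, as were the exocrine pancreas and liver lists. In comparisons of 5 against 5, a list that alone reaches that smallest p cannot pass after adjustment over the 36 lists. For the interaction the null of this test is no swim effect at either age, not equal swim effects at both ages. The median of a list is of edgeR log2 changes, those of the same setting in alternatives. Counts adjusted over the list alone use the p-values of that list's genes.

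Alternatives were RLE library sizes, the Wald test of DESeq2 1.42.0, no filter, a filter of at least 1 CPM in 5 libraries, voom with sample quality weights, limma-trend on the deposited scaled values (pseudocount 1 or 0.1, genes with at least 1 in 5 libraries, or all genes), only the 10 libraries compared, and leaving out each library in turn. Chosen after seeing the data were library totals without a TMM factor, RPKM with own totals, fits without the libraries with the highest epidermis score (1y_control 5, 3y_swim 1, 3y_swim 3), without those with the highest nerve score (1y_control 1, 1y_control 4), without those with the lowest TMM factor (1y_swim 2, 1y_swim 3), and a fit with epidermis, nerve, pancreas and liver scores as covariates. The pancreas score of every 1y_swim library lies above that of every other library, so these covariates take part of the group differences. Fewer calls with them therefore decide nothing in comparisons that hold 1y_swim. The correlation between effects was set against 99 relabellings, and counts of called genes against 100 splits of the libraries. The pipeline was tested on simulated data with 200 changed genes: it recovered 28 to 34% of changes of log2 1 and 65 to 74% of those of log2 2, with 103 to 112 calls of which 4 to 7 were false, and a list shifted by 0.5 was called in each of the 4 simulated comparisons with 0 of the other lists. Simulated genes varied independently, so the simulated list result does not cover lists whose genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with numpy 2.4.6.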

Results

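Read counts per Ensembl gene came from the muscle of male zebrafish, in 20 libraries of a 2 by 2 design of age and exercise. Fish were 1 or 3 years old. At each age 5 libraries came from fish exercised in a swim tunnel, a channel in which fish swim against a current, and 5 from fish with no perturbation, which gives the groups 1y_control, 1y_swim, 3y_control and 3y_swim. Library totals ran from 3.16e+07 to 4.89e+07 counts. Of the 32105 genes in the table, 5501 had 0 counts in all 20 libraries and 17025 were tested. The genes tested held 99.95% of all counts. Between libraries of the same group the correlation of log2 counts was 0.910 to 0.970. With n = 5 per group the median standard error of a log2 change was 0.276 to 0.278 in the 4 comparisons of groups and 0.391 for the interaction. The labels do not say how fish were paired, housed or timed, so the p-values measure the spread between these samples. Gene symbols stand as the annotation lists them, and genes are identified by Ensembl identifier without positions, since the table gives none.

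Markers of tissues next to muscle differed between libraries. A list score is the mean log2 level of a list's genes in a library, centred over the libraries. The epidermis score was 3.14 in 1y_control 5, 2.22 in 3y_swim 1 and 2.26 in 3y_swim 3. Nerve and glia markers stood highest in 1y_control 1 (score 1.18) and 1y_control 4 (1.76). Exocrine pancreas markers, a list chosen after seeing the data, had scores from 1.03 to 3.30 in the 5 libraries of 1y_swim. The 13 mitochondrially encoded genes of the respiratory chain also form a list tested below. They made up 13.0 ± 2.11% of counts in 1y_control, 14.6 ± 0.973% in 1y_swim, 11.57 ± 2.24% in 3y_control and 9.28 ± 0.766% in 3y_swim (SD, n = 5). That share was lower in 3y_swim than in 1y_swim by -5.31 points (two-sided exact permutation p = 0.00794, the smallest that 5 against 5 allows) and than in 3y_control by -2.29 points (exact permutation p = 0.0397), of which -1.38 remained without 3y_control 1. For 1y_swim against 1y_control and 3y_control against 1y_control the differences of 1.54 and -1.48 points gave exact permutation p = 0.198 and 0.302, and without 1y_control 4 they were 2.25 and -0.77; the first was 1.01 without 1y_control 2 and the second -2.39 without 3y_control 1. The TMM factor, which corrects for a few genes taking many of the counts, averaged 0.844 ± 0.121 in 1y_swim and 1.105 ± 0.0864 in 1y_control, a difference of -0.260 (exact permutation p = 0.00794).

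**Figure D1:**
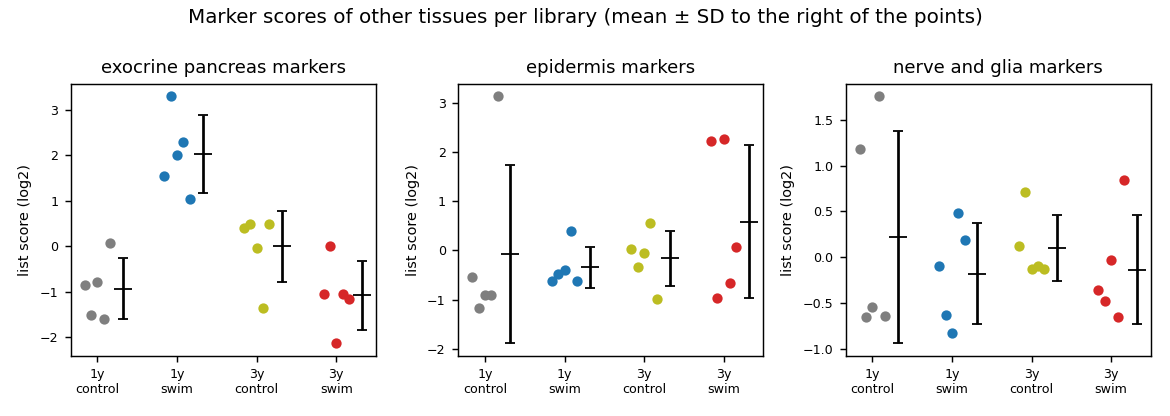
List scores of exocrine pancreas, epidermis and nerve markers in log2 units, 1 point per library, with the mean and SD of the 5 libraries of each group beside them. The pancreas scores of 1y_swim lie between 1.03 and 3.30, and 1y_control 5 has an epidermis score of 3.14.

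The swim effect at 1 year compares 1y_swim with 1y_control, younger fish with and without the swim tunnel. These groups also differed in pancreas markers and TMM factors (above), so a difference need not be an effect of exercise within muscle. With the swim tunnel 135 genes rose and 59 fell (edgeR quasi-likelihood test, n = 5 per group). PFKFB4 (ENSDARG00000029075), a bifunctional enzyme that sets the level of fructose 2,6-bisphosphate, went from 24.7 ± 19.7 to 135 ± 43.3 CPM (SD), a log2 change of 2.45 ± 0.57 (SE, adjusted p = 0.0453). The monocarboxylate transporters SLC16A4 and SLC16A3 (ENSDARG00000045051) rose by 2.81 ± 0.53 and 1.48 ± 0.30, and PDK2 (ENSDARG00000020876), a kinase that switches off pyruvate dehydrogenase, by 1.49 ± 0.33. LPIN1, which makes diacylglycerol, rose by 1.36 ± 0.27 and thrsp, a gene of fat synthesis, by 3.34 ± 0.77. In the glycolysis and glycogen list 2 of 45 genes rose and 43 did not pass, against 11 that rose adjusted over the list alone (median 0.28; adjusted p = 0.242 with an estimated correlation). In the hypoxia list 4 of 29 genes rose (10 rose and 1 fell adjusted over the list alone). They were PFKFB4, MXI1 (an antagonist of MYC) with 2.17 ± 0.36, vhl (part of the ligase that marks HIF for breakdown) with 1.35 ± 0.27 and ANKRD37 with 2.54 ± 0.60, the last named after its value was seen. That list had a median of 0.40 (adjusted p = 0.242 with an estimated correlation).

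The lists of mitochondrial respiration had positive medians in the swim effect at 1 year, with few genes that passed. In the list of nuclear-encoded respiratory chain genes 5 of 80 rose and 75 did not pass, against 71 that rose adjusted over the list alone (median 0.62, 80 of 80 positive; adjusted p = 0.243 with an estimated correlation). NDUFV1, a core subunit of complex I, rose by 0.79 ± 0.15 and atp5meb, a subunit of ATP synthase, by 0.80 ± 0.17; NDUFB4, uqcrc2a and COX6A1, named after their values were seen, rose by 0.66, 0.63 and 0.76. None of the 13 mitochondrially encoded genes passed over all genes and 8 rose adjusted over the list alone (median 0.48). None of the 24 citric acid cycle genes passed and 14 rose adjusted over the list alone (median 0.41). For fatty acid oxidation, PDK2 alone of 41 genes rose, and 7 did adjusted over the list alone (median 0.47). These lists were called upward by camera with its preset correlation, and adjusted p = 0.242 to 0.243 with an estimated correlation. Fry called 10 of the 36 lists. None passed the exact permutation test of scores (smallest adjusted p = 0.114), which no list can pass alone. At the same time 1y_swim had the lowest TMM factors and the pancreas markers given above. With library totals in place of TMM factors the median of all genes moved to -0.40 and the 4 list medians to 0.19, 0.09, 0.03 and 0.09. Each stayed above that of all genes, which was all but given, since this setting shifts all genes nearly alike.

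In the circadian clock list 2 of 44 genes rose, 1 fell and 41 did not pass (5 rose and 4 fell adjusted over the list alone), and camera did not call it (adjusted p = 0.837). The cryptochromes cry3b and CRY1 (ENSDARG00000011583), repressors of the clock, rose by 1.36 ± 0.20 and 1.72 ± 0.28, and NR1D1, named after its value was seen, fell by -2.14 ± 0.35. In the atrophy and autophagy list 3 of 56 genes rose (median 0.13): trim63b, a muscle ubiquitin ligase, by 1.77 ± 0.31, the transcription factor FOXO4 by 0.80 ± 0.14 and ATG14, named after its value was seen, by 0.55 ± 0.12. FBXO32, the other classical wasting ligase, had a log2 change of 2.45 ± 0.75 that did not pass in edgeR (adjusted p = 0.0965) and did in DESeq2. The cell cycle inhibitor CDKN1B (ENSDARG00000054271) rose by 1.31 ± 0.24 and TRIB3, a pseudokinase of the stress response, by 1.71 ± 0.36. Genes that fell included the receptor PDGFRA (-1.51 ± 0.25), which marks connective tissue cells, the growth factor FGF4 (-1.66 ± 0.38), the homeobox gene meox2b (-1.52 ± 0.33), the zinc finger genes ZIC1 (-1.44 ± 0.34) and ZNF503 (-1.45 ± 0.26), the splicing factor NOVA1 (-1.47 ± 0.26), AFAP1 (-1.48 ± 0.30) and LRRC8C (-1.46 ± 0.34). None of the 83 ribosomal protein genes passed over all genes, 59 rose adjusted over the list alone (median 0.52), and adjusted p = 0.471 with an estimated correlation. In the glucocorticoid response list PDK2 alone of 27 genes rose, with 10 higher and 1 lower adjusted over the list alone (median 0.79; adjusted p = 0.243 with an estimated correlation).

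Of the genes named, 4 protease genes of the pancreas had the largest rises at 1 year. The trypsin genes prss59.2 (ENSDARG00000073742), prss59.1 and prss1 rose by 4.14 ± 0.73, 4.07 ± 0.83 and 3.91 ± 0.71, and the elastase gene CELA1 by 4.11 ± 0.80. The apolipoprotein gene apoa1a rose by 2.85 ± 0.54. For prss1 the level went from 1.43 ± 1.02 to 21.6 ± 18.7 CPM. The stress protein gene nupr1b, which pancreas also expresses, rose by 2.68 ± 0.57. Of 23 exocrine pancreas genes tested, 17 rose (median 3.59, all 23 positive, exact permutation p of the score = 0.00794). This list was chosen after seeing the data and holds the 4 protease genes, so its values are not independent of theirs. Some members passed the filter mainly through 1y_swim, which favours positive changes. None of 27 liver genes passed in edgeR, although all 27 were positive (median 2.52, exact permutation p of the score = 0.0397). Of the other lists, proteasome, mitochondrial biogenesis, adipocyte, antioxidant, erythrocyte, fast fibre and ribosome biogenesis were called upward by camera with medians of 0.19 to 0.38, and adjusted p = 0.243 to 0.624 with an estimated correlation, the atrophy list included. Ribosome biogenesis lost its call with library totals (median -0.23, that of all genes -0.40). Leukocyte, interferon, neuromuscular and satellite cell lists were called downward with medians of -0.56 to -0.20, and adjusted p = 0.352 to 0.624 with an estimated correlation.

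Several of these list values at 1 year rest on 1 library. Without 1y_control 5, whose interferon score was 1.48, the interferon median went from -0.56 to -0.11 and its call was lost, as it was without 1y_swim 1. The same omission moved leukocyte markers to -0.25, the glucocorticoid list to 1.35 and fast fibre to 0.11 with its call lost. Without 1y_swim 3 ribosomal proteins stood at 0.25 and proteasome at 0.19, with calls kept, and antioxidant at 0.13, ribosome biogenesis at 0.09 and neuromuscular at -0.16, with calls lost. Hypoxia was 0.21 without 1y_swim 5, the glucocorticoid list 0.49 without 1y_control 1, atrophy 0.09 and 0.08 without 1y_control 1 and 2, and erythrocyte markers 0.40 and 0.39 without 1y_control 1 and 1y_swim 4. The calls of fast fibre and erythrocyte markers were each lost in 5 of the 20 fits and those of adipocyte, neuromuscular and satellite cell lists in 3. The 4 respiration lists kept theirs in all 20. Their medians ran from 0.43 (without 1y_swim 3) to 0.73 for nuclear and 0.39 to 0.58 for mitochondrially encoded genes. They ran from 0.30 to 0.49 for the citric acid cycle and 0.38 to 0.66 for fatty acid oxidation. The nuclear score of 1y_swim 3 was 1.14, with 0.0824 to 0.619 in the other libraries of 1y_swim.

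The count of 194 at 1 year moved with each of the 10 libraries compared, while genes at an unadjusted p under 0.05 numbered 2226 to 3755 in the 20 fits that left out a library (3274 with all). It was 8, 14, 6, 342 and 313 without 1y_control 1 to 5, 351, 8, 51, 344 and 84 without 1y_swim 1 to 5, and 126 without 3y_control 5; cry3b and CRY1 passed in all 20 of these fits. PDGFRA and MXI1 each failed in 2, the trypsin genes and CELA1 each in 4, FGF4 in 9, thrsp in 10, PFKFB4 in 12 and ZIC1 and LRRC8C each in 14, where their log2 changes stayed at -1.90 to -1.48 (FGF4), 2.46 to 3.63 (thrsp), 2.22 to 2.82 (PFKFB4), -1.69 to -1.13 (ZIC1) and -1.76 to -1.23 (LRRC8C). Library totals gave 78 higher and 1670 lower genes, and DESeq2 gave 901 genes. Leaving out the pair with the lowest TMM factors (1y_swim 2 and 3) gave 0 in edgeR (1668 at an unadjusted p under 0.05). Leaving out the pair with the highest nerve scores gave 9, and the 4 tissue marker scores as covariates gave 0 (819 unadjusted). The pancreas score was at least 1.03 in 1y_swim and at most 0.0574 in 1y_control. It nearly stands in for the group, so the count with covariates decides nothing.

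The swim effect at 3 years compares 3y_swim with 3y_control and asks what exercise changed in older fish. In edgeR 8 genes rose and 4 fell, with 1537 genes at an unadjusted p under 0.05. The fast myosin heavy chain gene myhz2 (ENSDARG00000012944) rose from 50.4 ± 19.2 to 254 ± 124 CPM, a log2 change of 2.34 ± 0.37 (adjusted p = 0.0368), and in both 1-year groups its mean was 233 and 235. AMD1 (ENSDARG00000043856), the S-adenosylmethionine decarboxylase of polyamine synthesis, fell from 53.4 ± 9.10 to 21.3 ± 2.45 (log2 change -1.32 ± 0.15, adjusted p = 0.000810). The mitochondrial chaperones HSPD1 and HSPA9 fell by -0.73 ± 0.13 and -0.67 ± 0.12, the fourth gene that fell being si:dkey-190l8.2 (-1.32, named after its value was seen). XPO1, a nuclear export receptor, rose by 1.08 ± 0.19 and the tetraspanin gene CD82 (ENSDARG00000019098) by 0.94 ± 0.17. The immediate early gene FOS did not pass (1.56 ± 0.86, adjusted p = 0.615), nor did PDK2 (ENSDARG00000020876) with -0.71 ± 0.32.

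By list, respiration had negative medians and immune and skin markers positive ones in the swim effect at 3 years. None of the 36 lists was called with an estimated correlation, by fry or by the exact permutation test (smallest adjusted p = 0.190). No list can pass that permutation test alone. None of the 80 nuclear respiratory chain genes, 13 mitochondrially encoded genes, 24 citric acid cycle genes or 41 fatty acid oxidation genes passed in edgeR. Adjusted over the list alone 0, 3, 2 and 0 of them fell. Their medians were -0.18, -0.36, -0.26 and -0.36, called downward by camera, and adjusted p = 0.513 to 0.664 with an estimated correlation. The nuclear respiratory list lost that call without 3y_control 1, where its median was -0.05. The chaperone list had 2 of 47 genes lower and 8 lower adjusted over the list alone (median -0.16; adjusted p = 0.513 with an estimated correlation). Camera also called proteasome, mitochondrial biogenesis and glycolysis downward with medians of -0.26 to -0.13, and adjusted p = 0.513 to 0.664 with an estimated correlation. Called upward were leukocyte (0.36), interferon (0.42), cell cycle (0.35), immediate early (0.30), ribosomal protein (0.27), fast fibre (0.17) and epidermis markers (1.46), and adjusted p = 0.599 to 0.664 with an estimated correlation. None of the leukocyte, interferon or epidermis genes passed in edgeR. The epidermis scores of 3y_swim 1 and 3 are given above, and the leukocyte scores of the same libraries were 1.01 and 0.953. Without the 3 libraries with the highest epidermis scores the epidermis median was -0.21, and without 3y_swim 1 or 3 alone 0.79 or 0.92. Without 3y_swim 4 interferon was 0.11 and ribosomal proteins 0.12. Other medians moved without 1 library to 0.20 to 0.71 for cell cycle, 0.11 to 0.31 for fast fibre, -0.25 to -0.08 for chaperones, -0.39 to -0.16 for proteasome and -0.20 to -0.07 for glycolysis, whose call was lost in 4 of 20 fits. Of 23 exocrine pancreas markers 18 were negative (median -1.26, exact permutation p of the score = 0.0714) and of 27 liver markers 21 (median -0.52, exact permutation p = 0.833), with none that passed in edgeR. In the circadian clock list none of 44 genes passed in edgeR, and adjusted over the list alone 7 rose and 2 fell.

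Most of the 12 calls at 3 years crossed the threshold when 1 library was left out, while AMD1 passed in all 20 fits. The number of calls was 6, 6 and 5 without 1y_control 1, 2 and 4, 6 and 1 without 1y_swim 1 and 2, 2, 7, 2, 1 and 1 without 3y_control 1 to 5, and 1, 1 and 2 without 3y_swim 3 to 5, and myhz2 failed in 8 of the 20, CD82 in 12, XPO1 in 14, HSPD1 in 15 and HSPA9 in 18. Their log2 changes stayed at 2.15 to 2.60 (myhz2), 0.85 to 1.005 (CD82), 0.99 to 1.23 (XPO1), -0.81 to -0.61 (HSPD1) and -0.73 to -0.57 (HSPA9). The value of FOS was 0.68 without 3y_swim 3. DESeq2 called 107 genes, library totals 0 higher and 3 lower, the fit without the epidermis-high libraries 2, and the fit with the 4 marker scores 0 in edgeR (1210 unadjusted).

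The age effect without exercise compares 3y_control with 1y_control and asks how the muscle of older fish differs at rest. In the older fish 112 genes rose and 91 fell. The circadian clock list held the widest change: 4 of its 44 genes rose, 11 fell and 29 did not pass, against 8 and 19 adjusted over the list alone. The nuclear receptor gene rorcb (ENSDARG00000017780) rose from 4.40 ± 2.13 to 39.3 ± 9.47 CPM (log2 change 3.15 ± 0.43, adjusted p = 0.00154). The repressors nfil3-5 and NFIL3 rose by 2.86 ± 0.46 and 2.13 ± 0.45. The output activator dbpa fell by -2.72 ± 0.33, and the period genes fell as well, PER1 (ENSDARG00000012499) by -1.75 ± 0.31, PER1 (ENSDARG00000056885) by -1.94 ± 0.37, PER2 by -1.69 ± 0.25 and PER3 by -1.87 ± 0.43. Since its members went both ways the list's median was -0.23, called downward by camera, with adjusted p = 0.833 with an estimated correlation, and the call was lost without 3y_control 1 (-0.11). The labels give no time of sampling.

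In the fast fibre list 1 of 48 genes passed, the fast myosin gene myhz2, which fell from 233 ± 48.6 to 50.4 ± 19.2 CPM (-2.21 ± 0.37). FST (ENSDARG00000052846), the gene of follistatin, which binds myostatin, rose by 1.74 ± 0.29. ASB15 (ENSDARG00000045863), a muscle ubiquitin ligase adaptor, rose by 3.04 ± 0.60, FOXO4 by 0.79 ± 0.14, the autophagy gene ATG14 by 0.64 ± 0.12 and the stress gene nupr1a by 1.77 ± 0.36. GPI (ENSDARG00000103826), a glycolytic enzyme, rose by 1.14 ± 0.26. The adhesion gene NCAM1 (ENSDARG00000007220) fell by -1.54 ± 0.27, the matrix crosslinking enzyme gene loxl2a by -1.75 ± 0.40, oaz2b, an antizyme that limits polyamine synthesis, by -2.26 ± 0.50, and the nucleotide carrier SLC25A33 by -2.11 ± 0.41. Its relative SLC25A32 (ENSDARG00000089791), a folate carrier, rose by 2.15 ± 0.35. Other rises were in CALCOCO1 (ENSDARG00000016391, 2.15 ± 0.50), the chemokine gene ccl34b.4 (1.76 ± 0.42), PHEX (0.91 ± 0.17), PHLDA3 (1.15 ± 0.27), UTP4 (0.91 ± 0.18) and NRF1 (0.63 ± 0.13), and other falls in the phosphate transporter SLC20A1 (ENSDARG00000010641, -1.71 ± 0.32), HIF1A (-0.51 ± 0.11), MYLK (ENSDARG00000034801, -0.52 ± 0.10) and rasip1 (-0.70 ± 0.14). The collagen gene col1a1a did not pass (-1.24 ± 0.48, adjusted p = 0.206).

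None of the 36 lists was called by fry. None passed the exact permutation test of scores (smallest adjusted p = 0.429), which no list can pass alone. Exocrine pancreas markers had a median of 1.16 (21 of 23 positive, exact permutation p of the score = 0.103) and liver markers of -1.02 (25 of 27 negative, exact permutation p = 0.206), with none that passed in edgeR. In the extracellular matrix list 1 of 101 genes fell and 9 did adjusted over the list alone (median -0.25). Camera called it downward together with cell cycle (-0.43), immediate early (-0.39, where both PER1 genes are the 2 that fell), cholesterol synthesis (-0.38), fatty acid oxidation (-0.32), fatty acid synthesis (-0.23) and mitochondrially encoded genes (-0.18), and adjusted p = 0.395 to 0.833 with an estimated correlation. Upward calls were ribosomal proteins (0.36), leukocyte (0.29), proteasome (0.19) and ribosome biogenesis (0.16), each with adjusted p = 0.833 with an estimated correlation. The extracellular matrix median was -0.17 without 1y_control 1 and -0.37 without 3y_control 1, with the call kept. Calls were lost for cholesterol synthesis without 1y_control 5 (-0.13), for fatty acid oxidation without 1y_control 4 (-0.11), for immediate early genes without 1y_control 2, 1y_control 5 or 3y_control 2 (-0.16, -0.24 and -0.26), for mitochondrially encoded genes in 6 of 20 fits (-0.32 to -0.11), for leukocyte markers in 3 (0.15 to 0.47), for ribosome biogenesis in 3 (0.10 to 0.195) and for proteasome in 2 (0.08 to 0.30). Cell cycle ran from -0.71 to -0.23 and fatty acid synthesis from -0.34 to -0.19 with calls kept. The count of 203 was 56, 64 and 102 without 1y_control 1, 3 and 4, 134 and 126 without 1y_swim 1 and 2, and 403, 87, 125, 99 and 106 without 3y_control 1 to 5; rorcb, nfil3-5, dbpa, PER2, both PER1 genes and myhz2 passed in all 20 of these fits, while GPI and loxl2a failed in 11, CALCOCO1 and ccl34b.4 in 13 and PHLDA3 in 14. DESeq2 called 720 genes, voom with sample weights 682, the fit without the nerve-high libraries 9, that without the epidermis-high libraries 115 and that with the 4 marker scores 14.

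The age effect with exercise compares 3y_swim with 1y_swim, older with younger fish after the swim tunnel. This was the widest contrast, with 1293 genes higher and 1717 lower in the older fish. Mitochondrial genes fell as a block. Of 80 nuclear respiratory chain genes 64 fell, 1 rose and 15 did not pass (74 lower adjusted over the list alone, median -0.87), and all 13 mitochondrially encoded genes fell (median -0.92). NDUFV1 (ENSDARG00000036438) fell from 751 ± 120.1 to 289 ± 41.0 CPM (log2 change -1.38 ± 0.16, adjusted p = 7.59e-05), NDUFS8 by -1.10 ± 0.14, MT-ND1 by -1.38 ± 0.17 and MT-ND2 by -1.23 ± 0.18. In the citric acid cycle 19 of 24 genes fell (21 adjusted over the list alone, median -0.70), among them citrate synthase CS (-0.68 ± 0.14), IDH3A (-1.16 ± 0.16) and IDH3G (-0.92 ± 0.12). In fatty acid oxidation 26 of 41 genes fell (34 lower and 1 higher adjusted over the list alone, median -1.21), with ACAA2, the last enzyme of the beta-oxidation spiral, at -2.29 ± 0.33 and the carnitine transferase CPT1B at -0.96 ± 0.24. PDK2 (ENSDARG00000020876) fell by -1.09 ± 0.33. The list tests gave adjusted p = 0.179, 0.0531, 0.0531 and 0.0531 with an estimated correlation, and each list passed the exact permutation test of its scores (adjusted p = 0.0286).

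In 6 further lists part of the genes fell in the same contrast. In glycolysis and glycogen 14 of 45 genes fell and 1 rose (17 and 1 adjusted over the list alone), in fatty acid synthesis 9 of 29 fell (11 and 1 rose adjusted over the list alone), in mitochondrial biogenesis 10 of 24 (11), in the glucocorticoid list 10 of 27 (13), and in the chaperone list 10 of 47 (11). In the hypoxia list 10 of 29 fell and 1 rose (13 and 2 adjusted over the list alone). Their medians ran from -1.11 to -0.30, and adjusted p = 0.0531 to 0.279 with an estimated correlation; in the exact permutation test the chaperone list did not pass (adjusted p = 0.0571) and the other 5 did. HSPA9 fell by -1.29 ± 0.13, HSPD1 by -1.13 ± 0.13, the import pore gene TOMM40 by -0.86 ± 0.11 and mgll, which splits monoglycerides, by -1.11 ± 0.13. The nuclear respiratory, mitochondrially encoded, citric acid cycle and fatty acid oxidation medians stayed under 0 in the fit with library totals, where the median of all genes moved to 0.29, as they did without the lowest TMM factors. Of the genes named, otoa (-5.81 ± 1.28) and CFAP58 (-5.12 ± 1.22) had the lowest values. The liver genes hpxa fell by -4.84 ± 1.08, apoa2 by -4.80 ± 1.09 and tfa by -4.39 ± 1.205, the apolipoprotein gene apoa1b by -4.58 ± 1.35, and the pancreas genes prss59.1 by -4.49 ± 0.85 and CELA1 by -4.44 ± 0.82. Of the pancreas and liver lists, chosen after seeing the data, 18 of 23 and 25 of 27 genes fell (medians -3.79 and -4.08, exact permutation p = 0.00794 for each).

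Leukocyte markers and part of the interferon and inflammation genes rose with age among exercised fish. Of 60 leukocyte markers 32 rose and 28 did not pass (46 higher adjusted over the list alone, median 1.14); of 41 interferon genes 12 rose and 29 did not pass (22, median 1.27); of 48 acute inflammation genes 17 rose, 6 fell and 25 did not pass (20 and 7, median 0.58). The list tests gave adjusted p = 0.137, 0.325 and 0.276 with an estimated correlation, and adjusted p = 0.0286, 0.0286 and 0.299 in the exact permutation test, which 13 of the 36 lists passed. The antigen-presenting gene mhc2dab rose by 3.91 ± 1.17 and igldcp by 3.33 ± 1.06; leaving out 1 library ended these calls in 5 and 6 of 20 fits, with 2.55 without 3y_swim 1 and 1.84 without 3y_swim 4. The interferon median was 0.81 without 3y_swim 4. METTL21C (ENSDARG00000078878), a muscle lysine methyltransferase gene, rose by 2.96 ± 0.52, nes, the gene of nestin, by 2.98 ± 0.88, actn2b, an actinin of the Z-disc, by 3.33 ± 1.04, gstk2 by 2.90 ± 0.81, txnb by 2.84 ± 0.92, FST (ENSDARG00000057992) by 1.69 ± 0.23 and PDGFRA by 1.84 ± 0.25. Of these, txnb failed in 5 of the 20 fits and was 1.24 without 3y_swim 4, nes failed in 5 (2.60 to 3.28), actn2b in 6 (2.42 to 4.08) and gstk2 in 1 (2.27 to 3.21). The endothelial receptor gene flt1 fell by -1.17 ± 0.17, and PER1 fell by -0.94 ± 0.31 (ENSDARG00000012499) and -1.41 ± 0.37 (ENSDARG00000056885). The first of these PER1 genes failed in 6 fits (-1.22 to -0.73), PDK2 in 5 (-1.35 to -0.90) and apoa1b in 4 (-4.88 to -3.96). Neither smyhc1 (-1.72 ± 0.68, and -0.94 without 1y_swim 5), which DESeq2 called, nor FOS (1.90 ± 0.88, and 1.06 without 3y_swim 3) passed in edgeR. The epidermis list, with 3 of 45 genes higher (1 adjusted over the list alone), had a median of 1.60 with adjusted p = 0.728 with an estimated correlation, and -0.12 without the 3 epidermis-high libraries; its call was lost without 3y_swim 1 (0.99) and without 3y_swim 3.

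**Figure D2:**
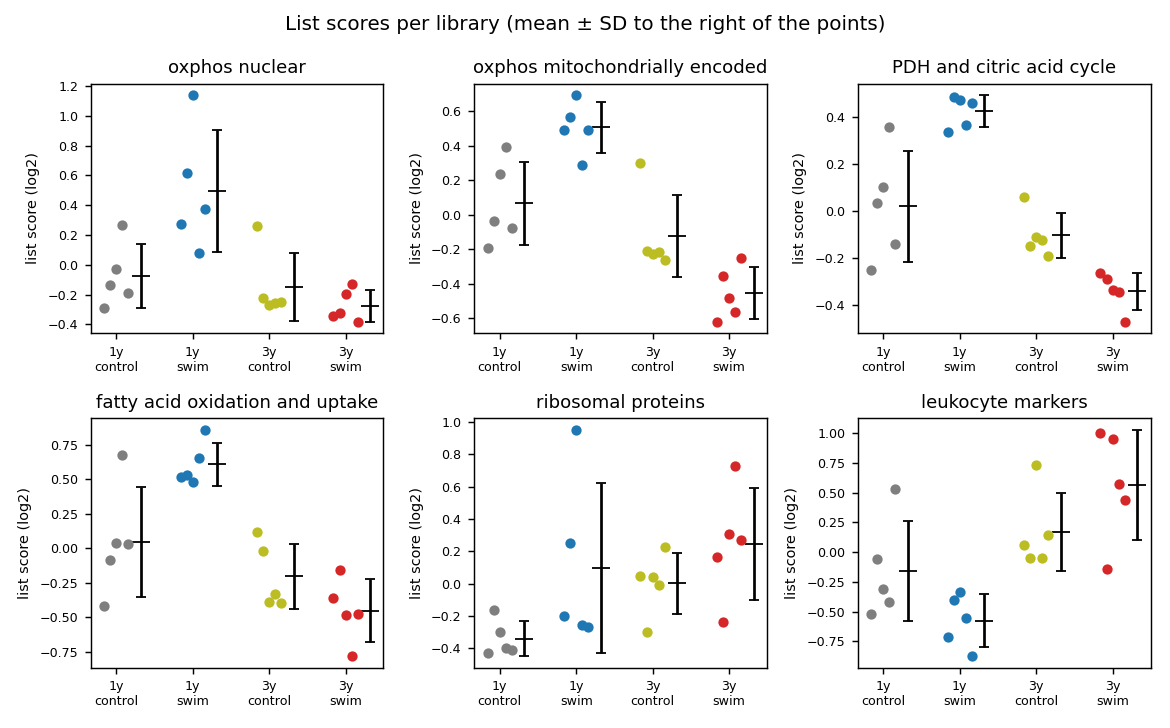
List scores in log2 units for 6 gene lists, 1 point per library, with the mean and SD of the 5 libraries of each group beside them. Scores of the nuclear respiratory chain list average 0.498 in 1y_swim and -0.275 in 3y_swim.

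Leaving out 1 library at a time kept the count of the age effect with exercise between 2198 and 3278. The hypoxia median was -0.30 without 1y_swim 5, and the 4 respiration lists moved by less. Library totals gave 2885 higher and 931 lower genes, and the deposited scaled values gave 1238. Leaving out the epidermis-high libraries (1y_control 5, 3y_swim 1 and 3y_swim 3) left 1429 genes. The 4 marker scores as covariates left 2 genes, both lower. Pancreas scores were at least 1.03 in 1y_swim and at most -0.00187 in 3y_swim. These covariates thus nearly stand in for the groups, and the count with them decides nothing.

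The interaction tests whether the swim effect differs between 3 and 1 years of age, as the swim effect at 3 years minus that at 1 year. In all 9 genes had a positive and 48 a negative interaction. Of the 48 negative ones 14 are exocrine pancreas markers, whose median was 3.59 in the swim effect at 1 year and -1.26 in that at 3 years (18 of 23 negative). Mitochondrial genes among them include the chaperones HSPD1 (-1.20 ± 0.18, adjusted p = 0.00885) and HSPE1 (-1.21 ± 0.22), the complex III assembly factor BCS1L (-1.37 ± 0.25), the import gene tomm40l (-1.70 ± 0.32), and the complex I genes NDUFV1 (-1.03 ± 0.22), NDUFS8 (-0.94 ± 0.20) and MT-ND1 (-1.13 ± 0.24). MT-ND1 averaged 4444 ± 816 and 6218 ± 445 CPM without and with the swim tunnel at 1 year, and 3724 ± 1065 and 2382 ± 307 at 3 years. PDK2 (ENSDARG00000020876, -2.20 ± 0.46), GPI (-2.01 ± 0.37) and FOXO4 (-0.998 ± 0.20) also had negative interactions, and TRIM71 (1.05 ± 0.22) and nfe2l3 (0.74 ± 0.15) positive ones. Of the digestive genes, CELA1 (-6.11 ± 1.102), prss59.1 (-5.76 ± 1.13), prss1 (-5.46 ± 0.97) and prss59.2 (-5.43 ± 0.99) had the lowest values of the genes named. FOS (3.55 ± 1.23) and FBXO32 (-2.92 ± 1.02) did not pass (adjusted p = 0.199 and 0.204).

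By list the interaction had negative medians for respiration. Of 80 nuclear respiratory chain genes 3 passed, all negative (62 adjusted over the list alone, median -0.79), of 13 mitochondrially encoded genes 1 (9, -0.85), of 24 citric acid cycle genes 0 in edgeR (20, -0.70), of 41 fatty acid oxidation genes 1 (17, -0.87), of 45 glycolysis genes 1 (2, -0.47), and of 24 mitochondrial biogenesis genes 0 (7 negative and 1 positive, -0.47). The list tests gave adjusted p = 0.0676 to 0.224 with an estimated correlation. In the exact permutation test, with swim labels permuted within each age, all 6 passed (adjusted p = 0.00227 to 0.0420). Its null is no swim effect at either age, so a pass does not by itself show that the effects differ between ages. Camera also called chaperone (3 of 47 genes negative), proteasome, hypoxia, antioxidant, glucocorticoid, fatty acid synthesis, ribosomal protein and ribosome biogenesis lists downward, with medians of -0.66 to -0.23 (adjusted p = 0.253 to 0.793 with an estimated correlation). Upward were leukocyte, interferon, epidermis, immediate early, acute inflammation and cell cycle lists with medians of 0.23 to 3.53 (adjusted p = 0.253 to 0.729 with an estimated correlation). The epidermis value turned to -1.45 without the epidermis-high libraries and was 0.80, its call lost, without 1y_control 5 alone. The interferon median of 0.99 was 0.45 without 1y_control 5 and 0.65 without 3y_swim 4, with the call kept. Ribosomal proteins stood at 0.03 without 1y_swim 3 and -0.16 without 3y_swim 2, the call lost in both, at -0.39 without 3y_swim 4, and turned to 0.19 without the pair with the lowest TMM factors. Ribosome biogenesis was -0.12 without 1y_swim 3 and hypoxia -0.20 without 1y_swim 5, both calls lost. Glucocorticoid ran from -0.69 to -0.22, fatty acid synthesis from -0.39 to -0.18 and cell cycle from 0.01 to 0.60, with calls lost in 9, 7 and 3 of 20 fits, and immediate early genes were 0.35 without 3y_swim 1.

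The 57 interaction calls fell to 5, 4 and 5 without 1y_control 1, 2 and 3, rose to 163 without 1y_control 4 and stood at 28 without 1y_control 5; they were 4, 22, 29 and 9 without 1y_swim 2 to 5, 26, 4 and 5 without 3y_control 1, 3 and 5, and 4, 3, 30 and 8 without 3y_swim 1, 3, 4 and 5. RLE sizes gave 31, DESeq2 407, and library totals 3 positive and 1 negative. The fits without the epidermis-high, nerve-high and lowest-TMM libraries gave 2, 3 and 5. The 4 marker scores gave 0 in edgeR (814 unadjusted), which decides nothing, since the pancreas score sets 1y_swim apart. HSPD1 failed in 1 of the 20 fits that left out a library. The other called genes named failed in 9 to 18 (CELA1, prss1 and prss59.2 in 9, NDUFV1 and PDK2 in 18).

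**Figure D3:**
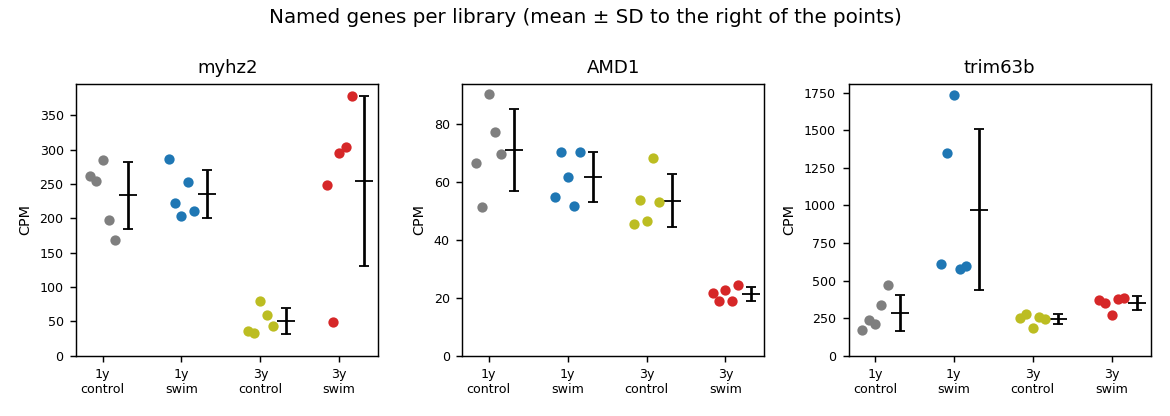
CPM of myhz2, AMD1 and trim63b, 1 point per library, with the mean and SD of the 5 libraries of each group beside them. The mean of myhz2 is 50.4 in 3y_control and 254 in 3y_swim, and that of AMD1 is 53.4 and 21.3.

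Across the 17025 genes the swim effects at the 2 ages, which share no library, had a Pearson correlation of -0.148 and a Spearman correlation of 0.0290, where genes are not independent replicates. In 99 relabellings of the libraries the Pearson value averaged -0.00703 (SD 0.240), and 58 were as far from 0. Leaving out 1y_control 5 turned the Pearson value to 0.157. Of the genes called at 1 and 3 years 1 was shared, si:ch73-141c7.1 (ENSDARG00000009040), which fell at 1 year and rose at 3 years. For the age effects without and with exercise the correlations were 0.356 (Pearson) and 0.402 (Spearman), and 7 of 99 relabellings gave a Pearson value as high, so this agreement is not beyond what relabelled libraries give. Leaving out 1y_control 5 raised it to 0.571, where the highest value of the relabellings of all 20 libraries was 0.570. Of the genes called in both, 58 rose and 58 fell in both, against 8.51 and 9.18 for independent calls, and 1 went each of the opposite ways. That reference takes genes as independent, which they are not, and no overlap from relabelled libraries was computed. Whether swimming at 3 years runs against the age difference was tested with the 3y_control libraries split between the contrasts: the Pearson correlation averaged -0.0158 (SD 0.0998 over 20 values). With shared libraries it was -0.313, and data simulated with no effect gave -0.491. The covariance had the opposite order, -0.115 with shared libraries and -0.102 (SD 0.00451 over 20) in data simulated with no effect. With split libraries the covariance averaged -0.00447 (SD 0.0517), so no direction is settled.

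Averaged over ages, 74 genes were higher and 33 lower with the swim tunnel. The kinase gene sbk3 rose by 2.34 ± 0.41, PFKFB4 by 2.21 ± 0.40, nupr1b by 2.13 ± 0.40, SLC16A4 by 1.96 ± 0.37 and the insulin receptor substrate IRS1 by 1.74 ± 0.36, while FGF4 (-1.17 ± 0.26), ZIC1 (-1.07 ± 0.24), ZNF503 (-0.96 ± 0.18), PDGFRA (-0.92 ± 0.17) and NOVA1 (-0.91 ± 0.18) fell. This count of 107 was 58, 47, 32 and 266 without 1y_control 1, 2, 3 and 5, 30, 46 and 53 without 1y_swim 2, 3 and 5, 66, 52, 52 and 70 without 3y_control 1, 3, 4 and 5, and 64 and 39 without 3y_swim 4 and 5. In the same 20 fits ZIC1 failed in 16 (-1.19 to -0.92), FGF4 in 15 (-1.28 to -1.08), IRS1 in 11 (1.42 to 1.89), NOVA1 in 8 (-1.02 to -0.82), ZNF503 and PDGFRA in 3, nupr1b in 2 and SLC16A4 in 1. Library totals gave 45 higher and 731 lower genes, with a median of all genes of -0.25. Averaged over exercise, 1629 genes rose and 1814 fell with age. Rises led with rorcb (2.83 ± 0.30), nfil3-5 (2.77 ± 0.32), mhc2dab (2.63 ± 0.78), prg4b (2.59 ± 0.90) and ASB15 (2.46 ± 0.42), falls with otoa (-3.19 ± 0.79), CFAP58 (-3.17 ± 0.79), apoa2 (-3.16 ± 0.72), hpxa (-3.02 ± 0.71) and the liver gene fabp10a (-2.94 ± 0.62). Of these prg4b failed in 14 of the 20 fits (2.12 to 3.71) and mhc2dab in 2 (1.68 without 3y_control 3). Library totals gave 2543 higher and 1160 lower genes with a median of all genes of 0.13, and the 4 marker scores left 315. Camera called 7 lists upward and 2 downward for the swim tunnel and 4 and 13 for age, none of which held with an estimated correlation (smallest adjusted p = 0.513 and 0.0605 with an estimated correlation).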

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

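The tests of pancreas and liver RNA and of library scaling for the digestive genes, and those of scaling, of the lowest TMM factors and of marker scores as covariates for mitochondrial genes, were chosen after the result was seen. Values were marked when 1 library stood apart from the other 4 of its group by Dixon's ratio, which chance does in about 1 of 20 groups. That held for 12 of 191 gene and group pairs and for 13 of 136 library measures and list scores.

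Among genes, CPM stood apart in 1y_swim 2 for apoa1a (34.01), hpxa (51.3) and apoa2 (220.05, the other libraries from 11.5 to 55.0). In 3y_swim 4 they did for igldcp (40.2) and txnb (63.2), in 3y_swim 1 for mhc2dab (50.9), in 3y_swim 5 for HSPD1 (25.6), and in 3y_swim 2 for prss59.1 (1.79) and CELA1 (2.33). HSPA9 was 193 in 3y_control 1, where the other libraries lay from 135 to 148. In 1y_control, library 4 had 3.72 for ASB15 (ENSDARG00000045863) and library 3 had 9.03 for FST (ENSDARG00000052846). The TMM factor of 3y_control 3 was 1.17, with 1.05 as the lowest of the others.

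Of the list scores, 3y_control 1 stood apart for the mitochondrially encoded (0.301) and the nuclear respiratory chain list (0.259), and 3y_control 2 and 3 for fast fibre (-0.297) and leukocyte markers (0.736). In 1y_control, library 5 had an epidermis score of 3.14 and an interferon score of 1.48, and library 2 a chaperone score of -0.127. In 1y_swim, library 3 had scores of -0.0941 for atrophy and -0.0918 for fatty acid synthesis, library 4 of 0.395 for epidermis and -0.137 for erythrocyte markers, and library 5 of 0.295 for mitochondrial biogenesis.

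A further 37 results differ in the swim effect between ages by the test of the interaction itself: the count of 57 genes, 16 named genes and 20 lists called by camera. Of the 20 lists 0 held with an estimated correlation and 6 in the exact permutation test. Epidermis (-1.45 without the epidermis-high libraries) and ribosomal proteins (0.187 without the lowest-TMM libraries) changed sign. For epidermis a lower median follows from leaving out the libraries with the highest score of that list. Without 1y_control 5 the interferon median was 0.45. The genes were TRIM71 (1.05), nfe2l3 (0.74), CELA1 (-6.11), prss59.1 (-5.76), prss1 (-5.46), prss59.2 (-5.43), PDK2 (ENSDARG00000020876, -2.20), GPI (ENSDARG00000103826, -2.01), tomm40l (-1.70), BCS1L (-1.37), HSPD1 (-1.20), HSPE1 (-1.21), FOXO4 (-0.998), NDUFV1 (-1.03), MT-ND1 (-1.13) and NDUFS8 (-0.94), all in log2 units. Lists with a positive median were epidermis (3.53), interferon (0.99), leukocyte (0.85), immediate early (0.55), acute inflammation (0.39) and cell cycle (0.23). Those with a negative median were fatty acid oxidation (-0.87), mitochondrially encoded (-0.85), nuclear respiratory chain (-0.79), citric acid cycle (-0.70), proteasome (-0.66), glycolysis (-0.47), mitochondrial biogenesis (-0.47), glucocorticoid (-0.47), antioxidant (-0.37), hypoxia (-0.36), chaperone (-0.33), ribosome biogenesis (-0.28), ribosomal proteins (-0.25) and fatty acid synthesis (-0.23).

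Digestive gland transcripts were higher on average in 1y_swim than in 1y_control. Liver markers were not confined to 1y_swim. Their score was 1.42 in 1y_control 1, 0.803 in 1y_control 4 and 1.24 in 3y_control 2. In every other library outside 1y_swim it was at most 0.0761 (1y_control 5). Within 1y_swim the liver score was 0.785 in library 3, 1.24 in library 5 and at least 2.03 in libraries 1, 2 and 4. The choice of scaling accounts for little of the higher pancreas values, whose median was 3.11 with library totals and 3.59 with TMM. The median of all genes moved only to -0.40 with library totals, so this test could hardly have come out otherwise. RNA from pancreas and from liver in these samples is a candidate source: all 23 pancreas and all 27 liver markers tested had positive changes (17 and 0 called, medians 3.59 and 2.52), with means in 1y_swim of 21.6 ± 18.7 CPM for prss1 and 16.2 ± 14.1 for CELA1, and 71.7 ± 85.0 for apoa2 and 71.0 ± 68.2 for tfa, with 53.0, 40.1, 220.05 and 167 in 1y_swim 2 alone and at most 23.3, 17.4, 55.0 and 114 in the other 4 libraries. Of these 0 pancreas and 1 liver genes stand in another list, and 6 and 12 averaged at least 1 CPM in the control libraries. The filter kept some mainly through 1y_swim, such as ctrb.2 with 0.272 to 5.14 CPM there and at most 0.110 in 1y_control. That all members tested were positive is thus partly given by how they were chosen and filtered. The labels name no step that would remove neighbouring tissue, and an effect of exercise on these genes within muscle was not tested.

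The score of the nuclear respiratory chain list changed with the swim tunnel by 0.57 ± 0.166 at 1 year and -0.13 ± 0.166 at 3 years, an interaction of -0.70 ± 0.235 (SE). Scaling is argued against as the whole cause of the interaction, since with library totals it was -0.41 ± 0.174, over 2 standard errors from 0, and without the libraries with the lowest TMM factors it was -0.43 ± 0.174, though the change at 1 year alone was 0.18 ± 0.123 with library totals, within 2 standard errors of 0. With the 4 tissue marker scores as covariates the value was -0.69 ± 0.492: the size held while its error grew, so RNA from skin, nerve or digestive glands cannot be told apart from the pattern, because these scores take part of the difference between groups. An effect of exercise that depends on age, as the design gives it, stays open as a hypothesis.

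Each count was compared with the counts of 100 splits of the libraries, the real grouping included, where under 5% argues against chance. For the swim effect at 1 year 1 split reached 194 genes (highest other 118), for the age effect without exercise 1 reached 203 (3), for the age effect with exercise 1 reached 3010 (980), for the interaction 1 reached 57 (2) and for the age effect averaged over exercise 1 reached 3443 (1), the real split each time. For the swim effect at 3 years 2 splits reached 12 genes (22) and for the swim effect averaged over ages 2 reached 107 (191). All 7 lie under that limit, but in the last 2 comparisons 1 other split gave more genes than the real groups. For the interaction the splits permuted swim labels within each age. They stand for no swim effect at either age, not for equal effects at both.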

How the results depend on the processing

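Settings chosen after the result was seen, tests included, are library totals, RPKM with own totals, the fits without epidermis-high, nerve-high or lowest-TMM libraries, the marker score covariates, the permutation test of list scores and the leave-one-out fits of lists; all others were chosen earlier. The cause was not tested for values that moved below, save where the construction of a setting shows it. Of 149 results of named genes, 149 held with the stricter filter, 146 of 148 with DESeq2 with 2 newly called (FBXO32 in the swim effect at 1 year, smyhc1 in the age effect with exercise), 142 with RLE sizes, 119 with voom weights, 115 with library totals, 106 without a filter, 111 of 143 with own-total RPKM, 86, 82 and 53 with the deposited values (pseudocount 1, 0.1, and 1 over all genes), 61 of 111 with 10 libraries, 104 without epidermis-high, 76 without lowest-TMM and 62 without nerve-high libraries, and 19 with covariates. Of 2980 leave-one-out fits of named genes 2323 kept the side of the threshold. Of 86 list calls 0 held with an estimated correlation, 31 with fry, 18 with the permutation test, 86 with RLE sizes, 74 without nerve-high, 73 without lowest-TMM, 71 without epidermis-high libraries, 71 with library totals and 59 with covariates; of 1720 leave-one-out values 1635 held.

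Counts that moved were, for the swim effect at 1 year, 901 with DESeq2, 93 without a filter, 321 with voom weights, 110, 128 and 46 with the deposited values, 3 with 10 libraries, 1748 with library totals, 1498 with own-total RPKM, 9 without nerve-high and 0 without lowest-TMM libraries, and 0 with covariates. For the swim effect at 3 years they were 107 with DESeq2, 1, 1 and 3 with the deposited values, 2 with 10 libraries, 3 with library totals, 7 with own-total RPKM, 2, 5 and 5 without epidermis-high, nerve-high and lowest-TMM libraries, and 0 with covariates. For the age effect without exercise they were 720 with DESeq2, 113 without a filter, 682 with voom weights, 43, 34 and 13 with the deposited values, 94 with 10 libraries, 115 without epidermis-high and 9 without nerve-high libraries, and 14 with covariates. The age effect with exercise gave 1238, 1325 and 1260 with the deposited values, 1429 without epidermis-high libraries and 2 with covariates. The interaction gave 31 with RLE sizes, 407 with DESeq2, 4 without a filter, 23 with voom weights, 11, 3 and 3 with the deposited values, 4 with library totals, 28 with own-total RPKM, 2, 3 and 5 without epidermis-high, nerve-high and lowest-TMM libraries, and 0 with covariates. The swim effect averaged over ages gave 455 with DESeq2, 61 without a filter, 181 with voom weights, 25, 22 and 1 with the deposited values, 776 with library totals, 1074 with own-total RPKM, 166, 11 and 3 without epidermis-high, nerve-high and lowest-TMM libraries, and 1 with covariates. The age effect averaged over exercise gave 1541, 1536 and 1644 with the deposited values, 2193 without nerve-high libraries and 315 with covariates. Where edgeR gave 0, genes at an unadjusted p under 0.05 numbered 1668 and 819 (swim at 1 year, lowest-TMM and covariates), 1210 (swim at 3 years) and 814 (interaction). DESeq2 gave the counts above on all libraries. Lower counts with covariates decide nothing where 1y_swim is compared, since its pancreas scores lie above all others.

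Leaving out 1 library gave ranges of 6 to 351 (swim at 1 year), 1 to 13 (swim at 3 years), 56 to 403 (age without exercise), 2198 to 3278 (age with exercise), 3 to 163 (interaction), 30 to 266 (swim averaged) and 2810 to 3797 (age averaged), -0.194 to 0.157 for the correlation of swim effects and 0.283 to 0.571 for that of age effects. With shared 3y_control libraries the correlation of the swim effect at 3 years with the age effect was -0.313, lower by construction. With covariates these genes turned direction: in the swim effect at 1 year prss59.2 (-0.55), CELA1 (-0.68), prss59.1 (-0.86) and prss1 (-0.51); in that at 3 years FOS (-0.31); in the age effect with exercise gstk2 (-0.0855), apoa1b (0.35), prss59.1 (0.36), CELA1 (0.31), tfa (1.08) and FOS (-0.40); and in the interaction prss59.1 (1.09), prss1 (0.54) and prss59.2 (1.28). For prss1, prss59.1, prss59.2, CELA1 and tfa this follows from the covariates, which hold these genes. Ribosome biogenesis in the swim effect at 1 year lost its call with library totals (-0.23) and without lowest-TMM libraries (-0.0369). With library totals the median of all genes moved to -0.40, which bears on the sign and not on the lost call. Epidermis turned without the epidermis-high libraries (-0.21 in the swim effect at 3 years, -0.12 in the age effect with exercise, -1.45 in the interaction). A lower epidermis median follows from this setting, which leaves out the libraries with the highest score of that list. Ribosomal proteins turned to -0.102 in the age effect with exercise with covariates. In the interaction they turned to 0.187 without lowest-TMM libraries and to 0.0286 without 1y_swim 3, where leaving out 1 library gave -0.39 to 0.03.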

Other observations

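The tests of the time of day, of library scaling and of marker scores as covariates for clock genes, and the exact permutation test of list scores, were chosen after the result was seen. Some gene groups of the age effect with exercise lie outside its account above. In the antioxidant list 10 of 35 genes fell (12 lower and 2 higher adjusted over the list alone, median -0.44; adjusted p = 0.405 with an estimated correlation and 0.0440 in the exact permutation test), among them SOD2 (-0.95), the mitochondrial superoxide dismutase, and gpx4a (-1.49), a glutathione peroxidase, both named after their values were seen. In the proteasome list 9 of 48 genes fell and 1 rose (20 and 2 adjusted over the list alone, median -0.46; adjusted p = 0.580 with an estimated correlation). Cholesterol synthesis had 4 of 27 genes lower and the endoplasmic reticulum stress list 5 of 34 (medians -0.40 and -0.17; adjusted p = 0.405 and 0.580 with an estimated correlation). No ribosomal protein gene of 83 passed in edgeR, with a median of 0.11 (adjusted p = 0.924 with an estimated correlation) that turned to -0.102 with the marker score covariates and was 0.40 without 1y_swim 3 and -0.03 without 3y_swim 4. Without 1y_swim 3 the antioxidant and proteasome medians were -0.24 and -0.27. Leaving out 1 library ended the call of ribosomal proteins and that of the endoplasmic reticulum stress list in 5 of 20 fits each. In the circadian list 5 genes rose and 16 fell with age among exercised fish.

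Lists of cell types and structure without a camera call in the age effect with exercise still held called genes. The extracellular matrix list had 8 genes higher and 12 lower of 101, the fast fibre list 6 and 1 of 48, the satellite cell list 6 and 2 of 38, the atrophy list 4 and 6 of 56, the immediate early list 5 and 3 of 56, the cell cycle list 2 and 3 of 60 and the neuromuscular list 1 and 3 of 24. Endothelial markers had 6 higher and 10 lower of 64, DNA damage genes 4 and 7 of 43, nerve markers 4 and 1 of 43, and the bone, cartilage and tendon list 1 and 2 of 36. The ribosome biogenesis list had 4 higher and 8 lower of 58 and the pigment cell list 1 and 2 of 23. Erythrocyte markers had 4 of 22 lower and the slow fibre list 2 of 25. Adipocyte markers had 4 of 22 lower and passed fry (adjusted p = 0.0332) and the exact permutation test (adjusted p = 0.0440). The 6 lists of endothelial cells, DNA damage, nerve and glia, bone and cartilage, pigment cells and slow fibres were called by camera in none of the 5 comparisons, with medians of -0.19 to 0.33 in this one.

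Clock genes differed between ages without exercise, 15 of them called. With library totals 14 kept their call and direction. The median of all genes moved only from 0.0056 to -0.025 there, so this outcome was all but given. It shows only that the choice of scaling mattered little in this comparison. A difference in the time of day at sampling is a candidate explanation. The median of 11 genes of the limb of bmal, clock, npas2, nfil3 and rorc was 0.87. That of 13 genes of the limb of per, dbp, ciart and nr1d was -1.66, a difference of 2.53, as a shift of phase would give. But the labels give no time and a change of the clock with age would look alike, so these cannot be told apart and both stay open. RNA from skin, nerve or digestive glands is argued against as the whole cause: with the 4 marker scores as covariates the median size was 1.66 (median standard error 0.41), against 1.75 (0.32) without them, with all 15 in the same direction and 14 at an unadjusted p under 0.05. Of the 15 calls 3 were kept, which decided nothing, since standard errors grew and 14 genes in all passed in that fit.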
